A study of Mus musculus with 12 samples.

How the data were processed

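Islets were isolated from KO and control C57BL/6 mice, RNA was extracted with Trizol and a miRNeasy kit and libraries followed a standard Illumina preparation, per the labels' protocols. Whether the libraries were stranded is not given in the sources used here. TopHat2, HTSeq, DESeq2 version 1.4.5 and the genome build mm9 are named in the submitters' processing notes, without the role of each. The gene annotation behind the counts is not given in the sources used here.

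One table of 23366 rows covered all 12 libraries. Per the file headers, it held raw read counts per gene, and the deposited count columns were whole numbers with different totals per library. The normalized values the authors deposited are a signal equal to the raw count divided by 1 factor per library, from 0.662 to 1.35, and they were used only for this check. The log2 fold change and the unadjusted p-value per gene in the authors' deposited table come from DESeq2, per the file headers; both were set beside the results obtained here. In 27 rows, with 0.0447% of all counts, the gene name had turned into a date, and these rows were left out.

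The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the raw counts, with TMM factors, the default expression filter (minimum count 10, minimum total 15), Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p, for 6 KO against 6 control libraries with no covariate. Values per library are CPM with TMM-scaled library sizes, and list scores are mean log2 CPM with a prior count of 2. The SE of a log2 fold change is its size divided by the root of the test's F statistic. The tests, the lists and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 50 counts in the higher group, or all that passed where fewer did, filled to 6 by the smallest p-values and given as not passing. It added Mcm7, Ins1, Ins2, Gcg, Sst and Ppy, and of each list or seed set up to 4 members past the threshold or, with none, the member with the smallest p; for the cholesterol synthesis and the Schwann and neuronal lists that member is not reported here. Mir17hg was too low to be tested, and its counts are given.

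Of 30 fixed gene lists, 25 were tested with camera of limma 3.58.1 at a correlation of 0.01, with an estimated correlation and fry as alternatives. Stellate and fibroblast, erythroid and adipocyte markers had 3, 0 and 2 tested genes, under the minimum of 5, and the sex-linked and cluster host genes were only described. All 12 libraries held counts of the Y-linked gene Ddx3y (96 to 240) and of Xist (15 to 44).

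Seed sites were 7mer matches in the longest annotated 3′ UTR of at least 20 bases per gene in the GENCODE annotation of GRCm38. This build differs from the authors' mm9, so the annotation served only for gene names, 3′ UTR sequences and the order of genes, and no coordinates are given. Of the rows, 23206 matched a gene name and 19886 had a 3′ UTR. Intervals of the seed set differences invert a two-sided exact permutation test of per-library means.

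The lowest and highest totals of 2643481 and 5101830 counts set the precision. Intervals and limits from counts cover counting error only, since reads are not independent molecules. Over the 66 pairs of libraries, counts differed by more than sampling noise (lowest chi-square per gene 1.52), so no library was counted as a copy of another. In 5 simulated data sets with genes drawn independently, built from the means, dispersions and library sizes of the 9664 genes of the KO and control comparison, with 200 changed genes, edgeR recovered 54.2% of changes of 1.5-fold and 85.6% of changes of 2-fold, and 5.16% of its calls were false. With no change simulated, it made at most 3 calls per data set.

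Alternatives fixed in advance were DESeq2 1.42.0, other scaling factors, other count filters, a block for the replicate number, covariates for acinar and Y-linked genes, a surrogate variable (sva 3.50.0), voom with quality weights, an adjusted p of 0.10, each library left out in turn, and for the sets other correlations, fry, 8mer sites and a correction for 3′ UTR length and GC content. Alternatives chosen after seeing the data leave out, or fit a term for, the 3 libraries of high acinar share, whose titles start with 701, 703 and 706, or fit a term for title numbers up to 706 against those from 805. What the title numbers stand for is not given in the sources used here. Figures were drawn with matplotlib 3.10.9.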

Results

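RNA of islets of Langerhans, the hormone-secreting cell clusters of the pancreas, was sequenced from C57BL/6 mice. The series title names the knockout (KO) by the microRNA clusters miR-17-92 and miR-106b, and the comparison asked which islet transcripts differ between KO and control. The series held 6 KO and 6 control libraries. No label says whether each library came from a separate animal, so the p-values below measure the spread between these libraries. Total counts per library ran from 2643481 to 5101830, with a mean of 3767104 ± 871298 in KO and 3700387 ± 1059691 in control libraries (SD, n = 6 each; two-sided exact permutation p = 0.892). The insulin genes Ins1 and Ins2 took 48.6% to 64.0% of the counts in each library, which left 1009760 to 1856671 counts for all other genes. Markers of acinar cells, the enzyme-secreting cells of the exocrine pancreas, took 14.5% of the counts in KO replicate 5, 11.5% in KO replicate 6 and 5.90% in control replicate 1. In the other 9 libraries the acinar share lay between 1.22% and 2.74%. Rn45s, the precursor of ribosomal RNA, took 5.11% of the counts in KO replicate 5 and 1.78% to 2.71% in the other 11 libraries.

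**Figure D1:**
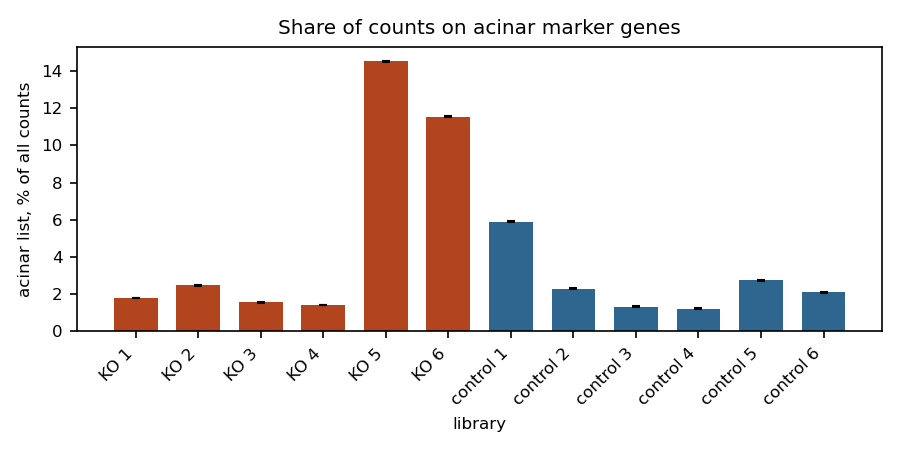
Share of all counts that fell on the acinar marker list, in percent, for each of the 12 libraries, with KO in red and control in blue. Error bars are exact 95% binomial intervals, which cover counting error only; KO replicates 5 and 6 at 14.5% and 11.5% and control replicate 1 at 5.90% stand above the rest.

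The transcripts that carry the deleted microRNAs were sparsely counted, and none of them could check the labels. Mir17hg, the long transcript of the miR-17-92 cluster, had 17 counts over the KO libraries and 11 over the controls, with 0 to 7 per KO library and 0 to 4 per control library. The KO to control ratio was 1.52 (95% interval from counting error only, 0.67 to 3.59), and the difference in CPM, the count scaled to the library total, did not pass a two-sided exact permutation test (p = 0.387, n = 6 each). Mcm7, a replication helicase gene whose intron holds the miR-106b cluster, was at 6.53 ± 0.37 CPM in KO and 5.82 ± 2.03 CPM in control islets (SD, n = 6 each). Its log2 fold change was 0.23 ± 0.22 (SE; adjusted p = 0.874, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The 9 microRNA precursor genes in the table had 0 counts in every library, which allows up to 1.14 CPM each in the library with the lowest total and 0.588 CPM in that with the highest, for counting error only. A count of 0 in control libraries as well means that these genes could not show the deletion in these counts, and the reason for the 0 counts was not tested.

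Few transcripts separated KO from control islets. Of 9664 genes tested, 12 passed an adjusted p of 0.05 (edgeR), 7 higher and 5 lower in KO. All 12 lay on the same side of the control mean in 6 of 6 KO libraries, but a test on these libraries picked them, so this adds no support. The largest rise was in Pdlim4, which encodes an actin-associated protein with PDZ and LIM domains. It went from 4.10 ± 0.65 to 12.05 ± 2.23 CPM (SD, n = 6 each), a log2 fold change of 1.61 ± 0.18 (SE; adjusted p = 4.25e-05). Its mean of 46 counts is under the minimum of the rule for named genes, and it was named after its values were seen. Among genes of the rule, Beta-s, an adult beta-globin gene, rose by a log2 fold change of 1.03 ± 0.20 (adjusted p = 0.030), and Chac1, a glutathione-degrading enzyme induced in the unfolded protein response, by 1.01 ± 0.17 (adjusted p = 0.00892). Cd59a, an inhibitor of the complement membrane attack complex, rose from 61.4 ± 6.23 to 95.8 ± 10.9 CPM, a log2 fold change of 0.63 ± 0.09 (adjusted p = 0.000656). Zfp330, a zinc finger gene, rose by 0.60 ± 0.11 (adjusted p = 0.0169) and Dio1, a deiodinase that activates thyroid hormone, by 0.57 ± 0.09 (adjusted p = 0.00860). Rab3c, a GTPase of secretory vesicles, rose by 1.12 ± 0.23 (adjusted p = 0.0392). Edem1, which directs misfolded glycoproteins to degradation, had a log2 fold change of 0.37 ± 0.08 and missed the threshold (adjusted p = 0.0538).

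The 5 genes lower in KO islets changed by less than 1 on the log2 scale. Basp1, a membrane-bound signalling protein, went from 15.9 ± 2.69 to 8.47 ± 1.67 CPM (SD, n = 6 each), a log2 fold change of -0.92 ± 0.16 (SE; adjusted p = 0.00945, edgeR). Gm11127 had a log2 fold change of -0.82 ± 0.15 (adjusted p = 0.0169) and Pigt, a subunit of the enzyme that attaches GPI anchors, of -0.72 ± 0.14 (adjusted p = 0.0379). Gpd2, the mitochondrial dehydrogenase of the glycerol phosphate shuttle, had -0.52 ± 0.10 (adjusted p = 0.0244). Cox7b, a subunit of cytochrome c oxidase, went from 132.1 ± 29.4 to 85.7 ± 12.7 CPM, a log2 fold change of -0.64 ± 0.13 (adjusted p = 0.0379). Control replicate 1 was at 76.5 CPM for Cox7b, inside the KO range of 65.3 to 98.1, while the other 5 controls lay between 131.5 and 161.0. Socs2, a feedback inhibitor of growth hormone signalling, had -0.54 ± 0.11 and missed the threshold (adjusted p = 0.0538). Reads of Beta-s can be shared with other globin copies, and exons of Gm11127 and Gpd2 overlap another annotated gene on the opposite strand, so these 3 values are less certain. Beta-s is annotated as Hbb-bs, which the erythroid marker list holds under that name only, so the list had 0 tested genes. Its member Alas2, under the expression filter, was at 2.65 ± 1.22 CPM in KO and 1.83 ± 1.10 CPM in control islets (SD, n = 6 each). Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 were at 0 CPM in both groups. Whether Beta-s came from red blood cells was not tested. The KO and control ranges did not overlap for 56 of the 9664 genes tested, where chance gives 0.216% of genes. Among the 12 genes this held for 7, but these were picked by a test on the same libraries, so it adds no support.

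The count of 12 depended on single libraries: leaving out KO replicate 1, KO replicate 4 or control replicate 5 lowered it to 5, 6 and 7. Of the genes tested, 764 had an unadjusted p under 0.05. Uniform p-values would give 483, a number that does not allow for structure among the libraries. The calls of 5 genes held in each of the 12 fits that left out 1 library: those of Pdlim4, Cd59a, Dio1, Chac1 and Basp1, with highest adjusted p-values of 0.000396, 0.00305, 0.0286, 0.0341 and 0.0445. Of these fits, Gm11127 kept its call in 9, Zfp330 in 7, Gpd2 and Beta-s in 4, Cox7b and Pigt in 3, and Rab3c in 2. DESeq2 called 27 genes, 10 higher and 17 lower, of which 10 were among the 12. In alternatives chosen after seeing the data, 30 genes passed without the 3 libraries of high acinar share, the 12 included, and 0 passed in edgeR with a term for sample title numbers up to 706 against those from 805, with 530 at an unadjusted p under 0.05. Only 1 control library has a title number up to 706, and with the term the SE of the 12 genes was 1.44 to 2.28 times as large; 8 of them had 82.6% to 148% of their log2 fold change, such as Cd59a with 0.63 ± 0.18, while Gpd2, Beta-s, Rab3c and Cox7b had 25.9%, 35.7%, 44.2% and -24.7%. In the authors' deposited table, 21 genes had p-values that passed after Benjamini-Hochberg adjustment here, and 9 of them were among the 12. Outside the 12, the authors' unadjusted p (DESeq2) was 1.63e-09 for Rps9, 2.25e-05 for Ccnd1 and 3.81e-05 for Sst. The log2 fold changes in the authors' deposited table had a Pearson r of 0.999 with those of edgeR across the tested genes, which are not independent replicates.

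**Figure D2:**
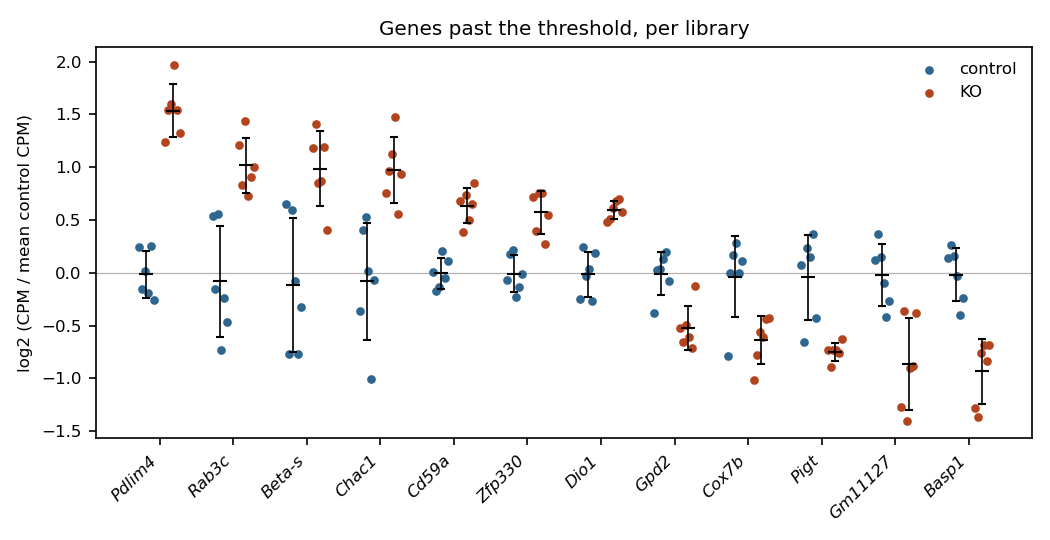
Log2 of CPM over the mean control CPM for the 12 genes that passed the threshold, per library, with KO in red and control in blue. Bars are the mean and SD of 6 libraries, and the log2 fold changes run from 1.61 for Pdlim4 to -0.92 for Basp1. All 12 lie on 1 side of the control mean in 6 of 6 KO libraries, which adds no support, since a test on these libraries picked them.

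None of the 5 hormone transcripts measured passed the threshold (edgeR). Ins1 was at 154824 ± 9876 CPM in KO and 154265 ± 9770 CPM in control islets (SD, n = 6 each), a log2 fold change of 0.01 ± 0.11 (SE; adjusted p = 0.993, edgeR), and Ins2 had a log2 fold change of -0.04 ± 0.11 (adjusted p = 0.968). Sst, the hormone of delta cells, was at 2169 ± 283 CPM in KO and 2885 ± 447 CPM in control islets, a log2 fold change of -0.41 ± 0.12 that missed the threshold in edgeR (adjusted p = 0.2998), although 6 of 6 KO libraries lay below the control mean. The unadjusted p of Sst in the authors' deposited table was 3.81e-05 (DESeq2). Glucagon (Gcg) of alpha cells had a log2 fold change of -0.41 ± 0.16 (adjusted p = 0.515). Control replicate 1 was at 12466 CPM for Gcg, against 5081 to 8032 CPM in the other controls. Pancreatic polypeptide (Ppy) had 0.61 ± 0.25 (adjusted p = 0.548). Of 36 tested genes of beta cell identity and glucose sensing, 0 passed over all genes tested and 0 adjusted over the list alone, and the list's median log2 fold change was 0.00 (camera adjusted p = 0.962). Its member with the smallest p was Neurod1, a beta cell transcription factor, at -0.25 ± 0.07 (adjusted p = 0.2998). The alpha cell list had a median of -0.17 (adjusted p = 0.138). It passed toward control without control replicate 2 (adjusted p = 0.0403, or 0.605 with an estimated correlation). With a term for title numbers, a fit carried by control replicate 1, its median was -0.35. Without the 3 libraries of high acinar share, that control among them, its median was -0.05 (camera adjusted p = 0.741). The delta and PP cell list had a median of 0.05 with a mean of -0.01 (adjusted p = 0.836), and Sst was the only member of the latter that passed when adjusted over the list alone.

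Of 25 gene lists tested with camera at a preset correlation of 0.01, 4 passed, 3 toward KO and 1 toward control. With an estimated correlation, 0 lists passed (lowest adjusted p = 0.190), and 0 passed with fry's test for a shift in 1 direction (lowest adjusted p = 0.0684). The mixed test of fry asks for changes of members in either direction. It passed for the G2/M, growth hormone, ER stress and reported target lists (adjusted p = 0.00186, 0.00186, 0.00259 and 0.0142). It also passed for the lists of cyclin-dependent kinases, beta cell identity and cholesterol synthesis (adjusted p = 0.0204, 0.0283 and 0.0454). The endoplasmic reticulum (ER) stress list rose relative to other genes (camera adjusted p = 0.000255; adjusted p = 0.558 with an estimated correlation), with 1 of 30 tested members past the threshold, 25 above 0 and 5 below, and a median log2 fold change of 0.08. Chac1 rose over all genes tested, and 3 members rose adjusted over the list alone, Chac1, Edem1 and Herpud1. Herpud1, a part of the ER degradation machinery named after its values were seen, had a log2 fold change of 0.30 ± 0.09 (adjusted p = 0.341). The cholesterol synthesis list fell (camera adjusted p = 0.0147; adjusted p = 0.190 with an estimated correlation), with 15 of 21 members below 0, a median of -0.10 and 0 members past the threshold. The cholesterol list did not pass without KO replicate 5 (adjusted p = 0.0530) or without control replicate 4 (adjusted p = 0.0527). With the term for title numbers, a fit carried by 1 control library, its median went from -0.10 to -0.0015. With the acinar covariate, the ER stress list was the 1 list that passed (adjusted p = 1.9e-06; adjusted p = 0.713 with an estimated correlation).

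The acinar list rose most (camera adjusted p = 6.81e-10; adjusted p = 0.558 with an estimated correlation), with a median log2 fold change of 1.19. Of its 29 tested members, 0 passed over all genes tested, and 22 rose adjusted over the list alone. Gp2, a zymogen granule protein, was at 431.3 ± 512.7 CPM in KO and 147.3 ± 85.6 CPM in control islets (SD, n = 6 each; adjusted p = 0.381, edgeR), and 3 of 6 KO libraries lay above the control mean. Without the 3 libraries of high acinar share the list's median was -0.06 and its direction turned (adjusted p = 0.795). With a term for them its median was 0.22 and it still passed toward KO (adjusted p = 7.79e-08; adjusted p = 0.647 with an estimated correlation). The macrophage and lymphocyte list rose with a median of 0.41 (camera adjusted p = 0.00953; adjusted p = 0.558 with an estimated correlation), with 0 of 15 members past the threshold. It did not pass without KO replicate 6 (adjusted p = 0.430), which held 74.0 CPM of the lymphocyte surface gene Cd52 against 4.06 to 10.6 in the other KO libraries. Its median was 0.11 without the 3 libraries of high acinar share (adjusted p = 0.812), and 0.26 with a term for them, where it passed (adjusted p = 0.0434; adjusted p = 0.647 with an estimated correlation). The ER stress and cholesterol lists still passed without these libraries (adjusted p = 0.00101 and 0.0192), with medians of 0.05 and -0.11, but with an estimated correlation their adjusted p-values were 0.714 and 0.356. Genotype and title number are fully confounded in that comparison. With all libraries and a term for title numbers, the ER stress median was 0.13 and the cholesterol median -0.0015.

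The other 21 lists did not pass, with camera adjusted p-values from 0.117 to 0.962. Of 51 tested genes reported as targets of the deleted clusters, 20 lay above 0 and 31 below, and the median was -0.05 (adjusted p = 0.579). The cell cycle gene Ccnd1 had a log2 fold change of -0.35 ± 0.09 (SE; adjusted p = 0.144, edgeR) and was the 1 target that passed adjusted over the list alone. In the list of cyclin-dependent kinases, cyclins D and inhibitors (median 0.00, adjusted p = 0.962), Ccnd1 and the inhibitor Cdkn1a, at 0.59 ± 0.18 (adjusted p = 0.2998), passed adjusted over the list alone, as did E2f4. The p53 and apoptosis list, which also holds Cdkn1a, had a median of 0.01 (adjusted p = 0.788). The G1/S and DNA replication list had a median of 0.15 (adjusted p = 0.495), with Tipin at 0.47 ± 0.22 (adjusted p = 0.614). The G2/M list had a median of -0.03, a mean of 0.00 and a camera direction toward KO (adjusted p = 0.702), and 2 of its 12 members, Bub3 and Spc25, rose adjusted over the list alone. The growth hormone and prolactin response list had a median of 0.01, a mean of -0.04 and a camera direction toward control (adjusted p = 0.373), while Socs2 and Cish were lower adjusted over the list alone.

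Lists of islet function did not pass. Insulin granule exocytosis had a median of -0.05 (adjusted p = 0.386), with the vesicle priming gene Cadps at 0.36 ± 0.10 (SE; adjusted p = 0.276, edgeR). The cAMP and protein kinase A list had a median of -0.02, a mean of 0.01 and a camera direction toward KO (adjusted p = 0.962), with Pkig, an inhibitor of that kinase, at 0.24 ± 0.10 (adjusted p = 0.580). MicroRNA processing genes had a median of -0.06 (adjusted p = 0.117), with the nuclease Drosha at -0.24 ± 0.10 (adjusted p = 0.580). The nuclear-encoded respiratory chain had a median of 0.00 over 67 genes (adjusted p = 0.836), of which Cox7b fell. Glycolysis and pyruvate dehydrogenase had a median of -0.03 (adjusted p = 0.836), with Pdhb at 0.35 ± 0.11 (adjusted p = 0.2998). Ribosomal proteins had a median of 0.05 (adjusted p = 0.262), while Rps9 was at -0.44 ± 0.09 (adjusted p = 0.0538) and was lower adjusted over the list alone. The ribosomal list passed toward KO without KO replicate 1, 2 or 4 or control replicate 1 or 4 (adjusted p = 0.0117, 0.0102, 0.0448, 0.0386 and 0.0155), but with an estimated correlation the adjusted p of these fits was 0.859 to 0.958. MicroRNA processing passed toward control without KO replicate 2 (adjusted p = 0.0402; adjusted p = 0.244 with an estimated correlation). The ribosomal list turned to a fall without the 3 libraries of high acinar share (median -0.07, adjusted p = 0.000319; adjusted p = 0.926 with an estimated correlation), and the respiratory chain fell (median -0.05, adjusted p = 0.00658; adjusted p = 0.926 with an estimated correlation). Immediate early genes had a median of 0.09 (adjusted p = 0.867), with Klf4 at -0.53 ± 0.23 (adjusted p = 0.591), and interferon-stimulated genes had 0.02, with a mean of -0.01 and a camera direction toward KO (adjusted p = 0.962) and Rsad2 at 0.41 ± 0.19 (adjusted p = 0.614).

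Marker lists of the remaining cell types did not pass. The list of genes silenced in mature beta cells had a median of 0.03 (adjusted p = 0.702), with Arhgdib at 1.42 ± 0.48 (SE; adjusted p = 0.381, edgeR), a value raised by KO replicate 6 at 33.0 CPM against 4.25 to 5.33 in the other KO libraries. Ductal markers had a median of 0.03 (adjusted p = 0.579), with the junction gene Cldn4 at -0.28 ± 0.08 (adjusted p = 0.232), which was lower adjusted over the list alone, where Tff2 was higher. Endothelial markers had -0.08 (adjusted p = 0.262), with Plvap at -0.36 ± 0.10 (adjusted p = 0.177), lower adjusted over the list alone. Schwann and neuronal markers had -0.25 (adjusted p = 0.1997).

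Genes with a seed site for the deleted microRNAs in the 3′ UTR did not pass a test for a shift in KO islets. Of 9664 tested genes, 9381 had an annotated 3′ UTR, and 3206 of these held a site for at least 1 of the 4 seed families. The 5 sets had camera adjusted p-values of 0.906 each, with a direction toward control, and the lowest unadjusted p was 0.431. For the miR-17 family, which includes miR-20a, miR-93 and miR-106b, 1392 genes had a site, and their mean level relative to genes without one differed between KO and control by -0.006 on the log2 scale (95% interval -0.038 to 0.023 by inverting a two-sided exact permutation test, p = 0.656, n = 6 each). The upper end corresponds to 1.64% higher expression in KO. The difference was -0.016 for miR-18 (882 genes, -0.050 to 0.016), -0.006 for miR-19 (1268 genes, -0.037 to 0.025) and -0.021 for miR-25/92 (730 genes, -0.060 to 0.019). For genes with any site it was -0.013 (-0.049 to 0.022). Of the 12 genes past the threshold, Rab3c and Cox7b had such sites, Rab3c with 2 for the miR-17 family and 2 for miR-25/92, and Cox7b with 1 for miR-18. When the counts of site-bearing genes were lowered by 0.05 on the log2 scale in the control libraries, camera gave an unadjusted p under 0.05 in 8 of 8 draws for the miR-17 family and for the set with any site. The draws reused the same libraries and differed only in the random thinning of counts, so 8 of 8 is not a detection rate. Every site-bearing gene was lowered by the same amount, and a shift of only part of them was not tried.

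**Figure D3:**
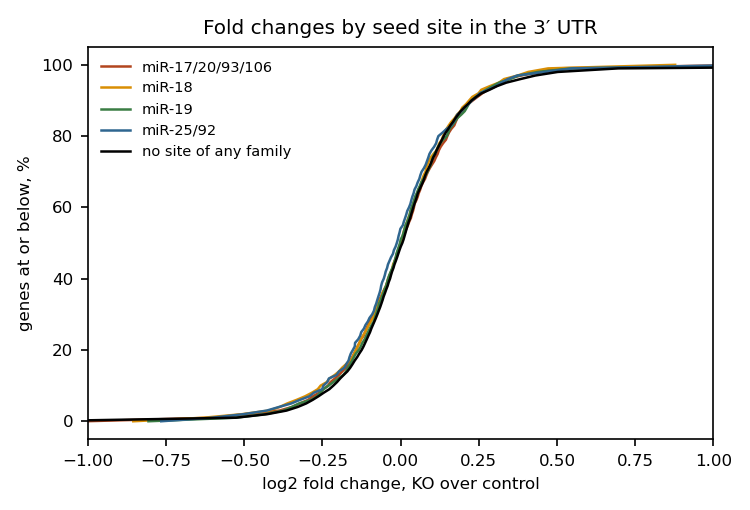
Percent of genes at or below each log2 fold change (KO over control), for genes with a seed site of each of the 4 families and for genes with no site. The horizontal axis is limited to -1 to 1 and the lines nearly coincide; the difference of medians between genes with and without a family's site was largest for miR-25/92, at -0.016.

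**Figure D4:**
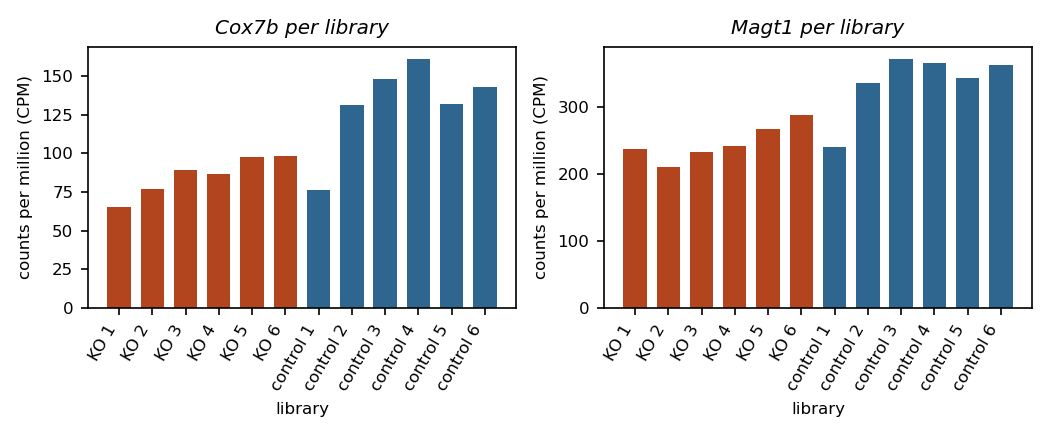
CPM of Cox7b and Magt1, neighbouring genes on the X chromosome, for each library, with KO in red and control in blue; Magt1 was chosen after its values were seen. Control replicate 1 sits at 76.5 CPM for Cox7b and 240.0 CPM for Magt1, inside the KO ranges and below the other 5 controls.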

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

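The tests of the title numbers, of control replicate 1, of the 3 libraries of high acinar share and of the splits by these libraries were chosen after the results were seen, and the test for a wrong label of control replicate 1 was set after 2 earlier forms of it, which had come out against a wrong label; the mean position given beside it is a further form, added last. The tests of acinar RNA on Cox7b and Magt1 and on the ER stress list replaced earlier ones: that on Cox7b left out the library in question, and that on the ER stress list had decided nothing. The counts over all splits were fixed before.

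A single library stood apart from the rest of its group in 12 of 136 groups of 6 values, where chance gives about 7; the Rn45s share was added to these after its values were seen. Rn45s took 5.11% of the counts in KO replicate 5 (1.78% to 2.71% in the other KO libraries). For KO replicate 6, Gpd2 was at 39.6 CPM (other KO libraries 26.3 to 30.7), Cd52 at 74.0 CPM (4.06 to 10.6) and Arhgdib at 33.0 CPM (4.25 to 5.33). The same library had a mean log2 CPM of 2.97 for genes silenced in mature beta cells (1.98 to 2.13 in the others) and of 4.15 for macrophage and lymphocyte markers (2.96 to 3.23). For control replicate 1, Cox7b was at 76.5 CPM (other controls 131.5 to 161.0), Gp2 at 309.7 CPM (78.6 to 160.6) and the acinar share at 5.90% (1.22% to 2.74%). Pdhb was at 37.1 CPM in control replicate 4 (23.8 to 27.6) and Tipin at 3.03 CPM in control replicate 2 (5.15 to 5.69). The G2/M list had a mean log2 CPM of 3.17 in control replicate 6 (2.92 to 2.97).

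Over all splits, chance is not excluded for the count of 12 genes between KO and control: of 100 splits of the 12 libraries into groups of 6, the real one included, 8 gave as many genes, and the highest other split gave 41. The high counts point to a structure of the samples: all 7 other splits with as many genes kept the libraries titled 701, 703 and 706 together. The 81 drawn splits that parted these libraries in any way gave at most 1 gene, so the count over all splits mixes this structure with chance. The real split sets 701 and 703 against 706, and splits of that form were not counted apart. The title numbers are a second structure: all KO libraries and control replicate 1 have numbers up to 706, and the other 5 controls have numbers from 805. Of 17 genes past the threshold in a fit without control replicate 1, 15 were also tested with all libraries, and of these that library was nearer to the KO mean for 8, among them Ccnd1, Gpd2, Deptor and Rab6a, and nearer to the other controls for Pdlim4, Cd59a, Chac1, Basp1, Dio1, Zfp330 and Gm11127. With a term for title number 0 genes passed (edgeR, 530 at an unadjusted p under 0.05): for 8 of the 12 the call ended with a wider SE and 82.6% to 148% of the log2 fold change, for Gpd2, Beta-s, Rab3c and Cox7b the fold change shrank or turned, and since 1 control library carries that fit, the deletion and a difference that follows the title numbers cannot be told apart.

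Cox7b and its X chromosome neighbour Magt1 were at the KO level in control replicate 1, at 53.8% and 67.6% of the mean of the other 5 controls, where the KO means were 59.6% and 68.9%. Acinar RNA is argued against as the cause, because KO replicates 5 and 6, with higher acinar shares, were above KO replicates 1 to 4 for both genes, with means of 123% for Cox7b and 120% for Magt1 of those of the latter. The deletion as the only cause would need control replicate 1 among the other controls, but it lay at least 7.32 SD of those 5 below their mean for both genes. Whether a KO library was labelled as control was not settled. Over 13 other genes, control replicate 1 was nearer to the KO mean for 6, or 46.2%. The share was 14.3% to 41.7% in the other controls and 53.8% to 100% in the KO libraries. Among the latter, only KO replicate 6 was under 75% (one-sided binomial p = 0.389 against that library). The count cannot decide, because it rests on few genes, and control replicate 3 (41.7%) and KO replicate 6 (53.8%) lie close. No conclusion on the label is drawn from it. The distances over the same genes lay nearer to the controls. On a scale from 0 at the KO mean to 1 at the control mean, both without the library judged, control replicate 1 had a mean position of 0.65 ± 0.18 (SE). The KO libraries had -0.13 to 0.34, with KO replicate 6 highest at 0.34 ± 0.10, and the other controls 0.66 to 1.11 (each by the genes of a fit without it). These SEs are over the genes of 1 library, which are not independent. This form was chosen after 3 others and does not settle the label. A sequence variant shared by the KO libraries and control replicate 1 was not tested.

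The acinar list was higher in KO (camera adjusted p = 6.81e-10; adjusted p = 0.558 with an estimated correlation; two-sided exact permutation p = 0.329 for its mean log2 CPM), and it and the lists that rose with it could reflect exocrine tissue carried into KO replicates 5 and 6 and control replicate 1, where the abundant Ctrb1 was at 9430 to 23500 CPM against 1907 to 3411 in the other libraries. Without these 3 libraries the acinar list's median log2 fold change went from 1.19 to -0.062, with mean levels of 7.70 to 8.29 log2 CPM in KO replicates 1 to 4 and 7.49 to 8.32 in control replicates 2 to 6, which restates how they were chosen and tests no cause. For the ER stress list, the values argue against such tissue as the whole cause, but its rise itself passed only at the preset correlation. The two-sided exact permutation p for its mean log2 CPM was 0.0303, or 0.253 adjusted over the lists. With the acinar covariate its median was 0.090 against 0.079 without (camera adjusted p = 1.9e-06, or 0.713 with an estimated correlation). Its mean log2 CPM, corrected for the acinar mean, differed by 0.15 ± 0.05 (SE). Without the 3 libraries its median was 0.051 (camera adjusted p = 0.00101, or 0.714 with an estimated correlation). The macrophage and lymphocyte list had a median of 0.11 without them, down from 0.41 and between the bounds set for and against such tissue, which stays open (adjusted p = 0.558 with all libraries and an estimated correlation). The number of lists past the threshold, 4, does not exclude chance, since 38 of 100 splits gave as many and the highest other split gave 7.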

How the results depend on the processing

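The alternatives on the 3 libraries titled 701, 703 and 706 and on title numbers, and the block with an estimated correlation, were chosen after seeing the data; all others were fixed before. For the 12 genes between KO and control, the count stayed within 1.5 times with RLE (12) or upper-quartile factors (12), a mean of at least 50 counts (9), the Y-linked covariate (11) and voom with quality weights (15). It moved to 27 with DESeq2, 22 without a count filter, 34 with the acinar covariate, 28 with the surrogate variable and 26 at an adjusted p under 0.10. It was 30 without the libraries titled 701, 703 and 706, 33 with a term for them, and 0 with a term for title numbers (edgeR, 530 at an unadjusted p under 0.05; DESeq2 was not run with that term), where 8 of the 12 genes had 82.6% to 148% of their log2 fold change with a wider SE, and Gpd2, Beta-s, Rab3c and Cox7b had 44.2% or less. Leaving out 1 library gave 5 to 17 genes. With the replicate block the count was 15, the 12 included; same-numbered libraries did not pair (correlations of deviations from -0.115 to 0.052), and no KO library correlated best with the control of its own number. The cause of these moves was not tested.

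Mcm7 did not pass in any setting run; its log2 fold change was 0.088 to 0.35 with 1 library left out and -0.035 with the title number term. The seed sets gave 0 calls in every setting run, 8mer sites and, for the 4 families, the length and GC correction included. Among 15302 heptamers present in at least 100 genes, the corrected statistic of the miR-17 family site ranked 4272 from the most raised, miR-19 3506, miR-18 8008 and miR-25/92 13859. Of the lists, 4 passed with the replicate block and 3 to 6 with 1 library left out. The count was 1 with the acinar covariate, 2 with the title number term (ER stress and alpha cell lists), and 0 with an estimated correlation, with fry's test for a shift in 1 direction, or with the block and an estimated correlation. The acinar list turned toward control with the acinar covariate (adjusted p = 0.862), without the 3 libraries (0.795) and with the title number term (0.0581), but still passed toward KO with a term for the 3 libraries (7.79e-08; adjusted p = 0.647 with an estimated correlation). The ribosomal list turned toward control without the 3 libraries (0.000319; adjusted p = 0.926 with an estimated correlation), and Cox7b turned to 0.16 with the title number term. Over all settings and named genes, 844 values kept direction and side of the threshold, 70 lost the call, 41 gained it, 8 moved and 1 turned; over single lists these were 421, 20, 9, 46 and 4. The variants for normalized values were not run, since counts were given. Depth limits genes outside insulin, which share 1009760 to 1856671 counts per library.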

Other observations

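The genes named in the next paragraph were chosen after their values were seen; the test on neighbours of the deleted loci and the splits for the seed sets were fixed before their results were seen.

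Without the 3 libraries of high acinar share, 13 genes were higher and 17 lower in KO islets, and all 12 genes of the full comparison were among them. Cdkn1a and Ccnd1, both on the list of reported targets, passed the threshold in opposite directions. Cdkn1a, an inhibitor of cyclin-dependent kinases, was higher by a log2 fold change of 0.81 ± 0.16 (SE; adjusted p = 0.00852, edgeR), and Ccnd1, a cyclin D, was at -0.36 ± 0.08 (adjusted p = 0.0265). Rab6a, a GTPase of Golgi traffic, was higher by 0.46 ± 0.08 (adjusted p = 0.00273). The ribosomal protein gene Rps9 was at -0.52 ± 0.08 (adjusted p = 0.000172), the lipid desaturase gene Scd2 at -0.47 ± 0.10 (adjusted p = 0.0188) and Deptor, an inhibitor of mTOR, at -0.81 ± 0.16 (adjusted p = 0.00852). Socs2 was at -0.56 ± 0.13 (adjusted p = 0.0366). In this comparison all 5 remaining controls have title numbers from 805 and all 4 remaining KO libraries have numbers up to 662, so genotype and title number are fully confounded. Control replicate 1, the only control numbered up to 706, is left out of it. That library was nearer to the KO mean for Rab6a and Deptor. It was inside the KO range for Ccnd1 (113.4 CPM against 99.6 to 121.6) and Cdkn1a (14.9 CPM against 10.6 to 23.1). The highest other control had 14.8 CPM of Cdkn1a. For Rps9 and Socs2, at 408.3 and 31.3 CPM, control replicate 1 lay above all KO libraries, on the control side.

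A hypothesis was that DNA of the targeted strain kept around the deleted loci could change nearby transcripts. Of the 80 tested genes nearest to Mcm7 or Mir17hg, 4 had an unadjusted p under 0.05, against 7.91% of all tested genes (exact one-sided hypergeometric test, p = 0.887), and 0 passed the threshold (edgeR; 12 passed over all genes). The test argues against a broad effect of this kind near the loci and says nothing on single genes.

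The smallest p of the 5 seed sets, 0.431, was reached or undercut in 63 of 100 splits of the libraries, the real one included, and the lowest of the other splits was 0.0122. Chance is not excluded for the seed sets.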
